A study of Homo sapiens with 18 samples.

How the data were processed

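The 18 libraries were made from LNCaP cells in 6 groups of 3 biological replicates: 3 siRNA pools (control, E2F1, E2F2), each with vehicle (ethanol) or 0.1 nM R1881. Per the labels, cells were transfected with Lipofectamine, total RNA was taken with Trizol and RNeasy columns, and libraries were made with an exon capture kit (TruSeq RNA Exome), so RNA outside the captured exons is measured only where it came through the capture. The submitters' notes name CASAVA 1.8.2, TopHat2 2.0.13, Picard 1.97 and featureCounts of Subread 1.6.4, with the GRCh38 genome, and give no settings. The deposited values are counts per gene, made by the authors with featureCounts per the labels; all were whole numbers of 0 or more, with 58037 gene identifiers, and no reads were processed again here. The strand setting, the handling of reads that map to several places and the annotation release were not given in the sources used here. Values for genes with near-identical copies, such as the replication histones and the UGT2B family, and for overlapping or antisense genes are therefore uncertain. Positions, GC content and gene length were taken from GENCODE 29, which held 57433 of the 58037 identifiers and 15122 of the 15185 tested.

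Libraries held 10930204 to 14819879 counts. Genes were kept by the edgeR filter on group (minimum count 10, minimum total 15), which left 15185 genes holding at least 99.9% of the counts of every library. Libraries were scaled by TMM factors. One model with 6 group means and no other term was fitted to all 18 libraries with edgeR 4.0.16 (quasi-likelihood F test) in R 4.3.3, and 11 comparisons were taken from it: R1881 against vehicle with each pool, each E2F pool against control with each treatment, the E2F pools against each other with each treatment, and the difference in R1881 response between each E2F pool and control. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and genes under 0.05 were called. The SE of a log2 fold change was its size divided by the square root of F. The common biological coefficient of variation was 0.167. Group values are means of TMM-scaled CPM ± SD (n = 3). Where a group held 0 counts over its 3 libraries the fold is a lower bound against 3 counts over the group, and with 1 to 3 counts the ratio is given with its 95% counting interval.

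The comparisons, tests, gene lists and most alternatives were fixed before the data were examined. The genes named were set by rule. E2F1 and E2F2 were always named. For R1881 with control siRNA and for each E2F pool against control, the 7 largest rises and 7 largest falls were taken among called genes with an average log2 CPM of at least 1 and no overlap between the groups, a condition that chance meets for 10% of genes with 3 against 3. For the other comparisons 4 and 4 were taken, without the overlap condition for the differences in response. From each list described, up to 4 called members with the smallest p were named, or up to 2 as values where none was called. Loci without a gene name were skipped, and genes of the lists are also named where their values in several comparisons are set side by side.

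The 20 gene lists were written from textbook knowledge: androgen-induced, androgen-repressed, G1/S and DNA replication, G2/M and mitosis, other E2F and RB family, G1 regulators, p53 targets, apoptosis, DNA repair, sterol and fatty acid synthesis, interferon response, endoplasmic reticulum stress, immediate early and serum response, MYC and ribosome biogenesis, glycolysis and hypoxia, neuroendocrine, luminal epithelial, markers of other cell types, replication histones and mitochondrially encoded genes. E2F1 and E2F2 are in none of them. Each was tested in each comparison with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation and with fry, adjusted over the 20 lists of a comparison. The similarity of the effects of the E2F pools was taken as the Pearson correlation and the covariance of log2 fold changes across genes, beside 100 simulations of unchanged groups with the same controls (negative binomial counts with the fitted means and dispersions) and beside the overlap that independent lists would give.

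Alternatives tried were RLE scaling, no filter on low counts, a filter of CPM of at least 1 in 3 libraries, DESeq2 1.42.0, limma-voom, a fit to the groups compared only, the replicate number as a block, thresholds of 0.01 and of 2-fold, and leaving out each library in turn. The labels do not say what libraries with one replicate number share, so the block was kept as an alternative. Its basis was checked by correlating deviations from the group mean between libraries of the same number: every such pair exceeded r = 0.1 in 8 of the 11 comparisons, and 11 of 18 libraries correlated best with a library of their own number. Differences between replicates were also compared with counting error by a chi-square per degree of freedom. Because replicate 3 stood apart there, replicates 1 and 2 only, offsets for GC content and length, and those offsets with the block were added after the data were seen. The method was tested on simulated data of the size of E2F1 siRNA against control with R1881 (15008 genes): edgeR recovered 25.4% of genes changed 1.5-fold, 62.7% at 2-fold and 95.5% at 4-fold, and 11 of its 140 calls were unchanged genes. With limma-voom these were 26.9%, 65.7% and 93.9% (11 of 142), and with DESeq2 37.3%, 77.6% and 95.5% (22 of 173).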

Results

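RNA was sequenced from LNCaP cells, an established androgen-responsive line of prostate cancer, kept in medium with charcoal-stripped serum, which is low in androgen. The cells received 1 of 3 siRNA pools (non-targeting control, E2F1 or E2F2), and then either vehicle (ethanol) or 0.1 nM of R1881, a synthetic androgen, for 48 h before harvest. The labels give the time from transfection to treatment as 42 h in one place and 48 h in another. The 6 groups held 3 biological replicates each, 18 libraries in all, with 10930204 to 14819879 gene counts per library. Of the 58037 genes listed, 15185 had enough counts to be tested. The labels name silencing of both E2F factors in growth-stimulated cells as the subject, so the comparisons ask what each siRNA pool changed with and without androgen, and what androgen changed with each pool. E2F1 and E2F2 are transcription factors that activate genes for entry into S phase.

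The 6 libraries of replicate 3 stood apart from their groups. Within a group, replicates 1 and 2 differed by a chi-square per degree of freedom of 1.79 to 4.42 across genes, and replicate 3 differed from either by 7.98 to 92.5. The largest values belonged to replicate 3 of control siRNA with vehicle. Fits to replicates 1 and 2 only hold 2 libraries per group. Their spread may leave out biological variation, so the higher counts they give below are not better estimates. The deviation of each replicate 3 library from the mean of the other 2 libraries of its group correlated across genes with GC content. Pearson r was 0.55 to 0.84 over 12097 genes, which are not independent replicates. Taken likewise, replicates 1 and 2 had r of -0.80 to -0.21, with replicate 3 among the libraries they were set against. Fold changes below are log2 values ± SE from one fit to all 18 libraries (n = 3 per group), with edgeR quasi-likelihood p-values adjusted by the Benjamini-Hochberg method. Intervals and floors given for low counts cover counting error only.

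Each siRNA pool lowered its target. E2F1 (ENSG00000101412.12, GRCh38 chromosome 20, 33675683 to 33686404) stood at 74.4 ± 6.32 CPM (SD, n = 3) with control siRNA and R1881, and at 9.69 ± 0.876 with E2F1 siRNA and R1881. That was 13.0% of the control level, a log2 change of -2.94 ± 0.17 (adjusted p = 2.50e-07). With vehicle, E2F1 went from 37.3 ± 5.00 to 6.83 ± 1.69 CPM, or 18.4% (log2 -2.45 ± 0.17, adjusted p = 5.11e-07). E2F2 (ENSG00000007968.6, chromosome 1, 23506430 to 23531220) was scarce to begin with, at 3.43 ± 1.12 CPM with control siRNA and R1881 and 2.29 ± 0.877 with vehicle. E2F2 siRNA left 0.195 ± 0.192 with R1881 (6.02%, log2 -4.05 ± 0.54, adjusted p = 3.73e-05) and 0.121 ± 0.142 with vehicle (5.67%, log2 -4.14 ± 0.63, adjusted p = 1.50e-04). These residual E2F2 levels rest on 1 to 5 counts per library with R1881 and 0 to 3 with vehicle, where a count of 0 allows up to 3. The E2F2 log2 change was -5.18 without replicate 3 of E2F2 siRNA with R1881, and -5.40 without replicate 1 of E2F2 siRNA with vehicle.

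Each pool was also examined for the other factor. E2F2 siRNA lowered E2F1 to 32.5% of control with R1881 (log2 -1.62 ± 0.16, adjusted p = 1.69e-06) and to 33.7% with vehicle (log2 -1.57 ± 0.16, adjusted p = 3.71e-06). E2F1 siRNA left E2F2 at 43.0% of control with R1881 (log2 -1.22 ± 0.38, adjusted p = 0.0586) and at 81.5% with vehicle (log2 -0.29 ± 0.38, adjusted p = 0.817), neither past the threshold at this depth. R1881 raised E2F1 1.99-fold in control cells (log2 1.00 ± 0.16, adjusted p = 1.73e-04). E2F2 changed by a log2 value of 0.56 ± 0.36 with R1881 in control cells (adjusted p = 0.275).

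**Figure D1:**
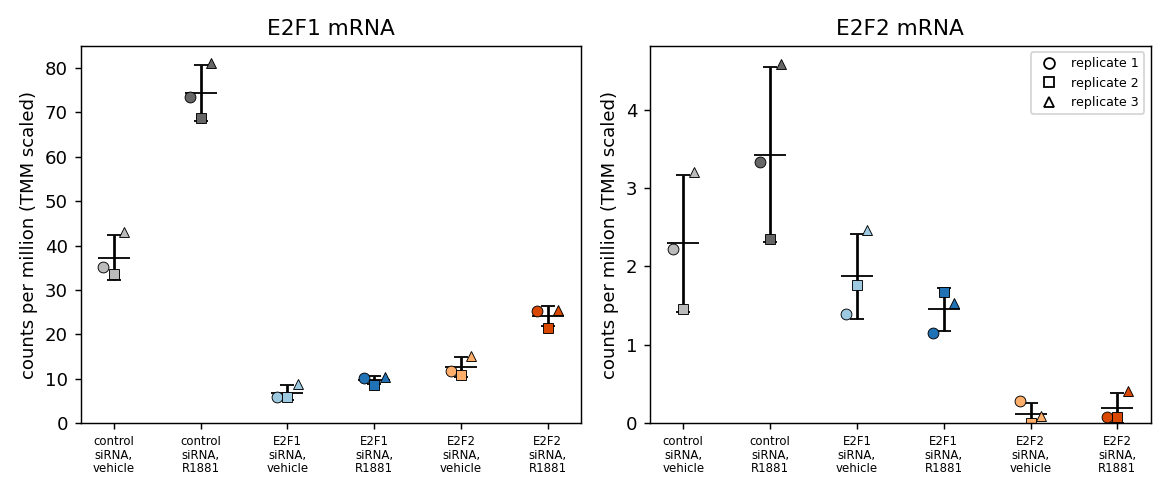
E2F1 (left) and E2F2 (right) mRNA in CPM, scaled by TMM factors, in each of the 18 libraries; the horizontal axis gives the 6 groups, symbols the replicate number, and bars the mean ± SD (n = 3). E2F1 fell from 74.4 to 9.69 with E2F1 siRNA and to 24.1 with E2F2 siRNA under R1881.

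**Figure D2:**
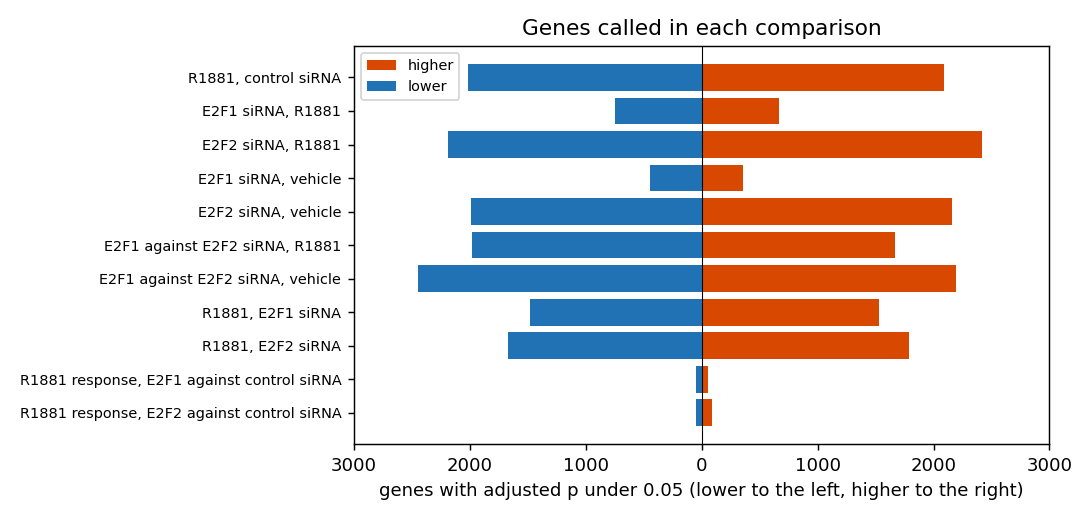
Genes with an adjusted p under 0.05 in each of the 11 comparisons, with lower genes drawn to the left and higher genes to the right (edgeR quasi-likelihood, 18 libraries). E2F2 siRNA changed 4601 genes under R1881 and 4145 under vehicle, and E2F1 siRNA 1418 and 802.

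R1881 in cells with control siRNA switched on the classical androgen-induced genes. KLK3, which encodes prostate-specific antigen, rose 15.4-fold (log2 3.95 ± 0.13), KLK2 45.2-fold (log2 5.50 ± 0.16) and TMPRSS2, a surface protease, 7.90-fold (log2 2.98 ± 0.10). CHRNA2, a nicotinic receptor subunit, rose from 1.14 ± 0.327 to 66.4 ± 9.52 CPM (SD, n = 3). The amino acid transporter SLC38A4 (ENSG00000139209.15, chromosome 12, 46764761 to 46832408) and the glucose transporter SLC2A3 had 0 counts with vehicle, and were at least 112-fold and at least 61.1-fold higher with R1881 against a floor of 3 counts over the group. STEAP4, a metalloreductase, had 2 counts with vehicle and 506 with R1881 (ratio 265, 95% counting interval 73.0 to 2195), and CTNNA2 had 1 and 78 (ratio 81.7, interval 14.2 to 3269). CCDC141 (log2 7.69 ± 0.36) and PGC, which encodes a gastric protease precursor (log2 5.95 ± 0.39), also rose. Large falls included DAB1 (log2 -5.19 ± 0.41), CCDC80 (-4.98 ± 0.31), AOC1, a diamine oxidase (-4.35 ± 0.40), MYOZ1 (-4.10 ± 0.29) and DAPK1, a death-associated kinase (-3.77 ± 0.25). IL1B, a cytokine gene, went from 85 counts to 2 (ratio 40.6, interval 10.9 to 340.4).

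Of 35 androgen-induced genes tested, 34 rose with R1881 (35 adjusted over the list alone), and of 16 androgen-repressed genes 15 fell (15 adjusted over the list alone), among them LRRN1 (log2 -3.12 ± 0.10), the opioid receptor gene OPRK1 (-3.80 ± 0.15) and CAMK2N1 (-1.95 ± 0.09). Cell-cycle genes rose with them. Of 42 genes for G1/S transition and DNA replication, 35 rose (40 adjusted over the list alone), with FEN1 at 2.11-fold, CDC6 at 2.29-fold and TYMS, thymidylate synthase, at 1.98-fold. Of 45 genes for G2/M and mitosis, 41 rose (44 adjusted over the list alone), with KIF20A at 2.45-fold and AURKA at 2.16-fold. Lipid synthesis genes rose in 22 of 30 cases (23 adjusted over the list alone), among them ACACA, which makes malonyl-CoA (1.89-fold). The list of MYC and ribosome biogenesis genes, below called MYC-driven as a name only, rose in 19 of 22 cases, with ODC1 at 2.49-fold. MYC itself was not called (log2 0.34 ± 0.19, edgeR adjusted p = 0.223). The list of endoplasmic reticulum stress genes rose in 14 of 25, with CREB3L4 at 2.23-fold. The camera test called these 7 lists with its preset correlation (adjusted p = 0.0025 or lower) and with an estimated correlation (adjusted p = 0.0369 or lower).

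The DNA repair list also rose with R1881, in 26 of 32 members, and its call was lost with adjusted p = 0.152 with an estimated correlation; UBE2T rose 2.09-fold and FANCI 1.93-fold. Calls were lost likewise for other E2F and RB family genes (4 of 15 rose and 2 fell; adjusted p = 0.319 with an estimated correlation), glycolysis and hypoxia genes (11 of 20 rose and 2 fell; adjusted p = 0.305 with an estimated correlation) and replication histones (18 of 49 rose and 1 fell; adjusted p = 0.536 with an estimated correlation). The other 9 lists were not called. Among p53 targets 3 of 27 rose and 9 fell, among interferon response genes 2 of 30 rose and 5 fell, and among G1 regulators 6 of 13 rose and 1 fell, that one being the cyclin-dependent kinase inhibitor CDKN1A (log2 -0.83 ± 0.12). Among 12 luminal keratins and related genes 3 rose and 2 fell, among 6 tested markers of other cell types 1 rose and 2 fell, and among 16 serum response genes 3 rose and 1 fell. The apoptosis list had 2 of 19 members lower, BMF (4.00-fold) and CASP9 (log2 -0.58 ± 0.16), and the neuroendocrine list 2 of 5, ENO2 (-0.81 ± 0.16) and SYT1 (-1.63 ± 0.55). MT-CO1, of the mitochondrially encoded list, had a log2 value of -0.15 ± 0.09 (adjusted p = 0.221). With the replicate block MT-CO1 and MT-CO3 passed (log2 -0.16 and -0.12, edgeR adjusted p = 0.0206 and 0.0466). In each comparison where a list's median, mean and test differed in sign, the test did not call the list.

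In total R1881 changed 4105 of the 15185 genes in control cells, 2093 higher and 2012 lower, and 1245 of them by 2-fold or more. With the replicate number as a block the count was 6392, and with replicates 1 and 2 only 7205. A fit to the 6 libraries compared gave 1842.

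E2F1 siRNA in androgen-treated cells lowered cell-cycle genes and raised interferon response genes. MCM10, a replication initiation factor, fell by 1.07 ± 0.10 on the log2 scale, the phosphatase gene CDC25A by 1.04 ± 0.10, and RRM2, a subunit of ribonucleotide reductase, by 1.32 ± 0.14. Of the 42 G1/S and replication genes 33 fell (38 adjusted over the list alone), and of the 45 G2/M and mitosis genes 33 fell (42 adjusted over the list alone), with CDCA8 lower by a log2 value of -1.28 ± 0.11 and BIRC5, which encodes survivin, by -0.89 ± 0.09. Replication histones fell in 30 of 49 cases, and DNA repair genes in 14 of 32 (21 adjusted over the list alone), with FANCD2 at -0.77 ± 0.11. E2F7 (-1.36 ± 0.16) and E2F8 (-1.13 ± 0.16), which encode repressive E2F factors, fell, as did the kinase inhibitor genes CDKN2C (-1.29 ± 0.16) and CDKN2D (-1.33 ± 0.19).

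The interferon-stimulated genes IFI27 (ENSG00000165949.12, chromosome 14, 94104836 to 94116698) and IFI6 rose 17.1-fold (log2 4.10 ± 0.34) and 5.78-fold (log2 2.53 ± 0.18) with E2F1 siRNA under R1881, OAS2 11.3-fold (log2 3.50 ± 0.51), and BST2 and IFITM1 6.41-fold and 5.37-fold. Of 30 interferon response genes 15 rose (19 adjusted over the list alone). Androgen-induced genes were higher still than with R1881 alone in 13 of 35 cases (21 adjusted over the list alone), among them FKBP5, a co-chaperone (1.85-fold), STEAP4 (4.12-fold) and SLC45A3 (1.74-fold). KLK3 had a log2 value of 0.39 ± 0.12 (adjusted p = 0.0511). Androgen-repressed genes fell in 5 of 16 cases and 1 rose, with PEG3 lower by -1.08 ± 0.10. ACTA2, smooth muscle actin, rose 5.47-fold (log2 2.45 ± 0.18), and SPRY4, an inhibitor of growth factor signalling, 4.94-fold. Besides E2F1 itself, large falls included TENM2 (log2 -1.86 ± 0.44), RDM1, a recombination factor (-1.69 ± 0.21), NAV3 (-1.67 ± 0.18), FAM49A (-1.67 ± 0.30), SCARA3 (-1.67 ± 0.27) and DMBX1 (-1.63 ± 0.30).

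With an estimated correlation 9 of the 14 lists called remained so: androgen-induced, G1/S, G2/M, G1 regulators, DNA repair, lipid synthesis, interferon response, endoplasmic reticulum stress and MYC-driven genes. The calls were lost for replication histones (adjusted p = 0.0536 with an estimated correlation), androgen-repressed genes (adjusted p = 0.0870), other E2F and RB genes (0.0846), serum response genes (0.0870) and mitochondrially encoded genes (0.451). The genes changed by E2F1 siRNA under R1881 numbered 1418, 671 higher and 747 lower, and 255 by 2-fold or more. The count was 3022 with the replicate block, 4487 with replicates 1 and 2 only, 2131 in a fit to the 6 libraries compared and 903 with no filter on low counts. Without control siRNA with R1881 it was 897 (replicate 1) and 872 (replicate 2), and without E2F1 siRNA with R1881 it was 877, 899 and 915 (replicates 1, 2 and 3).

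E2F2 siRNA in androgen-treated cells also lowered cell-cycle genes. TYMS fell 3.53-fold (log2 -1.82 ± 0.09), MCM4, part of the replicative helicase, 2.81-fold (-1.49 ± 0.08), BIRC5 3.89-fold (-1.96 ± 0.10) and TPX2, a spindle factor, 3.39-fold (-1.76 ± 0.09). Of the 42 G1/S and replication genes 40 fell (42 adjusted over the list alone), of the 45 G2/M and mitosis genes 43 fell (45 adjusted over the list alone), and of 32 DNA repair genes 26 fell (27 adjusted over the list alone), with CLSPN at -1.64 ± 0.13. The MYC-driven ribosome biogenesis genes fell in 20 of 22 cases (22 adjusted over the list alone), including NOLC1 (2.00-fold) and FBL, fibrillarin (log2 -1.15 ± 0.09). Replication histones fell in 37 of 49 cases and rose in 2. CDKN1A, which encodes p21, rose 4.04-fold (log2 2.02 ± 0.12), while SKP2, which promotes degradation of kinase inhibitors, fell (-1.23 ± 0.13).

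Of the 30 interferon response genes, 22 rose with E2F2 siRNA under R1881 (24 adjusted over the list alone), with IFI27 at 14.8-fold, OAS2 at 11.0-fold, OASL at 7.47-fold and IFI6 at 5.97-fold. Androgen-induced genes were higher in 14 of 35 cases and lower in 1. Androgen-repressed genes were higher in 7 of 16 cases and lower in 1, with CAMK2N1 at 3.28-fold and UGT2B17, a steroid-conjugating enzyme, at 4.10-fold. KCNK3, a potassium channel gene (ENSG00000171303.6, chromosome 2, 26692690 to 26733420), had 2 counts with control siRNA and 201 with E2F2 siRNA (ratio 113.8, 95% counting interval 31.1 to 946.0). AOC1 rose 28.5-fold (log2 4.83 ± 0.40), ABCG2, a drug efflux transporter, 15.0-fold (3.90 ± 0.41), S1PR3, a sphingosine 1-phosphate receptor, 14.1-fold (3.81 ± 0.13) and SLC1A2, a glutamate transporter, 12.4-fold (3.63 ± 0.33). Large falls included PIF1, a DNA helicase (-2.29 ± 0.22), ADRA2A, an adrenergic receptor (-2.12 ± 0.17), IQGAP3 (-2.06 ± 0.19) and the histone genes HIST2H2AB (-2.20 ± 0.24), HIST2H3D (-2.17 ± 0.33), HIST1H4A (-2.09 ± 0.33) and HIST1H2AJ (-2.04 ± 0.40).

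The G1/S, G2/M, DNA repair, interferon and MYC-driven lists kept their calls with an estimated correlation. The other 4 of the 9 lists lost them: androgen-induced (adjusted p = 0.278 with an estimated correlation), androgen-repressed (adjusted p = 0.278), other E2F and RB genes (0.0865) and replication histones (0.0756). The p53 targets (adjusted p = 0.0697) and lipid synthesis genes (0.0545) were not called, nor were they with an estimated correlation (0.0961 and 0.314). Both passed with the replicate block (0.0092 and 0.0041), with fry (3.74e-05 and 2.71e-04) and with replicates 1 and 2 only. Fry tests a list against no change rather than against the other genes. The lipid synthesis list also passed without replicate 3 of control siRNA with R1881 and without replicate 3 of E2F2 siRNA with R1881 (0.0334 and 0.0102). MALAT1, a nuclear non-coding RNA chosen after its values were seen, took 4.58 ± 0.408% of counts with E2F2 siRNA and R1881 (SD, n = 3), against 1.61 ± 0.314% with control siRNA and R1881. E2F2 siRNA changed 4601 genes under R1881, 2416 higher and 2185 lower, and 1345 by 2-fold or more. The count was 6919 with the replicate block and 7828 with replicates 1 and 2 only.

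**Figure D3:**
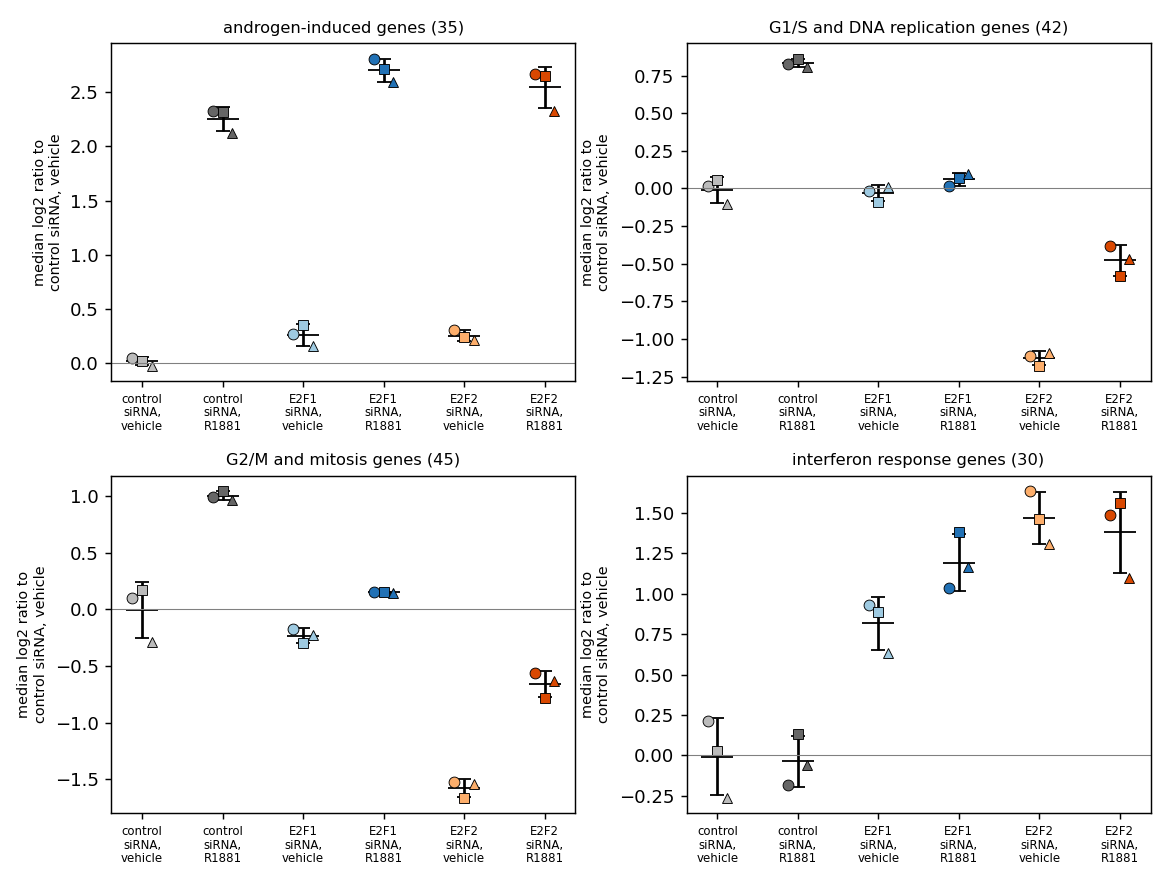
Median over the members of 4 gene lists of the log2 ratio to the mean of control siRNA with vehicle, one point per library, by group on the horizontal axis; symbols give the replicate and bars the mean ± SD (n = 3). For the G1/S genes, control siRNA with R1881 lay at 0.81 to 0.86, E2F1 siRNA with R1881 at 0.01 to 0.09, and E2F2 siRNA with vehicle at -1.18 to -1.09.

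Without androgen, few cell-cycle genes were called with E2F1 siRNA. CDC25A (log2 -0.65 ± 0.10), RRM2 (-0.59 ± 0.14) and MCM3 (-0.41 ± 0.10) were the 3 of 42 G1/S genes that fell, while CDC6 rose (0.35 ± 0.09), and the list was not called (adjusted p = 0.312). Of the G2/M genes 4 of 45 fell (6 adjusted over the list alone), CDCA8, PRC1, SPAG5 and KIF20A, by -0.56 to -0.41. That list's call was lost with adjusted p = 0.152 with an estimated correlation. Its log2 median against the mean of control siRNA with vehicle was 0.10, 0.17 and -0.29 in replicates 1, 2 and 3 of that group. With E2F1 siRNA and vehicle it was -0.17, -0.30 and -0.23, so the list lay lower in replicates 1 and 2 and not in replicate 3. Interferon response genes rose in 12 of 30 cases (16 adjusted over the list alone), with IFI27 at 7.03-fold (log2 2.81 ± 0.32), OAS2 at 8.58-fold (3.10 ± 0.58) and IFI6 at 4.17-fold (2.06 ± 0.18); this call held with an estimated correlation (adjusted p = 2.87e-04). Some androgen-induced genes rose with no androgen added, 6 of 35, with KLK2 at 2.11-fold and KLK3 at 1.88-fold, while 3 fell. Among androgen-repressed genes 5 of 16 fell and 1 rose; PEG3 fell 3.49-fold and OPRK1 by 1.22 ± 0.13 on the log2 scale.

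Large rises with E2F1 siRNA under vehicle also included GBP1, a guanylate-binding protein induced by interferon (log2 3.31 ± 0.46), SERPIND1, which encodes heparin cofactor II (3.06 ± 0.16), TRGC1 (2.59 ± 0.28), CXCR4, a chemokine receptor (2.28 ± 0.22), and ELOVL2, a fatty acid elongase (2.20 ± 0.61). Large falls besides E2F1 and PEG3 included IL1B (-3.02 ± 0.41), AOC1 (-2.90 ± 0.35), P3H2, a collagen-modifying enzyme (-2.63 ± 0.18), MYRF (-1.76 ± 0.37) and ARHGAP31 (-1.75 ± 0.36). Of the 10 lists called, the interferon list alone held with an estimated correlation; the others had adjusted p = 0.0656 to 0.562 with an estimated correlation.

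The genes changed by E2F1 siRNA under vehicle numbered 802, 359 higher and 443 lower, and 220 by 2-fold or more. The count was 1934 with the replicate block, 2864 with replicates 1 and 2 only, 462 with no filter on low counts and 17 in a fit to the 6 libraries compared. Without E2F1 siRNA with vehicle it was 445 (replicate 1) and 460 (replicate 2).

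E2F2 siRNA without androgen again lowered the cell-cycle lists. Of the 42 G1/S genes 35 fell (39 adjusted over the list alone), with MCM10 at -1.74 ± 0.10 and TYMS at -1.55 ± 0.09, and of the 45 G2/M genes 41 fell (43 adjusted over the list alone), with PTTG1, securin, at -1.90 ± 0.12. The MYC-driven list fell in 15 of 22 cases (17 adjusted over the list alone), and interferon response genes rose in 22 of 30 (24 adjusted over the list alone), with RSAD2, viperin, at 8.01-fold and IFIT3 at 5.82-fold. Of 27 p53 targets 14 rose (15 adjusted over the list alone), with CDKN1A at 5.62-fold (log2 2.49 ± 0.12), GDF15, a stress cytokine, at 7.34-fold (2.88 ± 0.28), and SPATA18 at 2.49-fold. These 5 lists kept their calls with an estimated correlation (adjusted p = 4.86e-04 or lower).

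KLK3 was 2.01-fold lower with E2F2 siRNA under vehicle, while the androgen-induced genes ALDH1A3, MAF and SLC45A3 rose 1.76-fold, 1.68-fold and 1.59-fold. Of the 35 androgen-induced genes 8 rose and 4 fell, and the list was not called (adjusted p = 0.533). Large rises included KCNK3 (33.7-fold, log2 5.08 ± 0.26), CXCR4 (26.2-fold, 4.71 ± 0.20), NPPC, a natriuretic peptide gene (13.5-fold, 3.76 ± 0.48), OAS2 (12.5-fold, 3.64 ± 0.56), ABCG2 (11.1-fold, 3.48 ± 0.31), CCDC144CP (10.6-fold, 3.41 ± 0.28) and IFI27 (10.2-fold, 3.35 ± 0.31). ADRA2A (log2 -2.70 ± 0.17), NMU, a neuropeptide gene (-2.32 ± 0.31), DAB1 (-2.24 ± 0.31), SERPIND1 (-2.24 ± 0.29) and the histone genes HIST1H2AL (-2.26 ± 0.36), HIST1H2AH (-2.26 ± 0.36) and HIST1H2AJ (-2.24 ± 0.44) fell.

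Calls were lost for DNA repair, where 19 of 32 fell (adjusted p = 0.0939 with an estimated correlation), replication histones, where 39 of 49 fell (0.0939), other E2F and RB genes (0.404), lipid synthesis (0.250), and glycolysis and hypoxia (0.626). The other E2F and RB list and the glycolysis list lost their calls with the replicate block too (adjusted p = 0.0564 and 0.0517). MALAT1 took 6.35 ± 1.00% of counts with E2F2 siRNA and vehicle (SD, n = 3), against 2.57 ± 1.15% with control siRNA and vehicle. E2F2 siRNA changed 4145 genes under vehicle, 2156 higher and 1989 lower, and 1239 by 2-fold or more. The count was 6873 with the replicate block, 6962 with replicates 1 and 2 only and 1793 in a fit to the 6 libraries compared.

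Compared directly under R1881, cells with E2F2 siRNA had lower cell-cycle genes than cells with E2F1 siRNA. Of the 42 G1/S genes 28 were higher with E2F1 siRNA (30 adjusted over the list alone), with TYMS 2.15-fold and CDC6 2.21-fold higher, as were 35 of the 45 G2/M genes, with PTTG1 at 2.27-fold, and 19 of the 22 MYC-driven genes. CDKN1A was lower with E2F1 than with E2F2 siRNA (log2 -1.85 ± 0.12), as were the androgen-repressed genes CAMK2N1 (-2.55 ± 0.09) and PEG3 (-1.95 ± 0.10). NCAPD3, a condensin subunit (ENSG00000151503.12, chromosome 11, 134150119 to 134225454), stood at 1116 ± 47.2 CPM with E2F1 siRNA and 186.8 ± 43.9 with E2F2 siRNA under R1881 (SD, n = 3; log2 2.58 ± 0.15). ADRA2A (2.88 ± 0.17), GSTA1, a glutathione transferase (2.54 ± 0.17), and ACTA2 (2.50 ± 0.18) were also higher with E2F1 siRNA. ABCG2 (-6.16 ± 0.54), AOC1 (-5.85 ± 0.45) and GIMAP6 (-4.56 ± 0.35) were lower, and KCNK3, at 0 counts with E2F1 siRNA, was at least 70.4-fold higher with E2F2 siRNA.

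Under vehicle 36 of 42 G1/S genes were higher with E2F1 than with E2F2 siRNA (36 adjusted over the list alone), and 41 of 45 G2/M genes and 18 of 22 MYC-driven genes were higher too. Of the p53 targets 13 of 27 were lower with E2F1 siRNA and 1 was higher. SERPIND1 (log2 5.30 ± 0.22), GSTA1 (2.83 ± 0.16), GRIN3A (2.81 ± 0.11) and TTR, transthyretin (2.77 ± 0.25), were higher with E2F1 siRNA, and IL1B (-5.87 ± 0.34), AOC1 (-5.71 ± 0.38), ABCG2 (-4.80 ± 0.35) and P3H2 (-4.00 ± 0.18) were lower. KLK3 was 3.77-fold higher with E2F1 siRNA than with E2F2 siRNA (log2 1.91 ± 0.12). With an estimated correlation, the androgen-repressed, G1/S, G2/M and MYC-driven lists held of 9 called under R1881, and the G1/S, G2/M, p53 and MYC-driven lists of 10 called under vehicle. The interferon list was lower with E2F1 siRNA under vehicle in 10 of 30 cases, with adjusted p = 0.0244, or 0.260 with an estimated correlation and 0.0520 with the replicate block. The markers of other cell types (6 tested) were called lower in both, with adjusted p = 0.212 and 0.260 with an estimated correlation and 0.0504 and 0.0562 with the block; VWF, a clotting factor gene, was lower in both (log2 -1.35 ± 0.16 and -2.69 ± 0.16). In total 3648 genes differed under R1881 (1664 higher and 1984 lower with E2F1 siRNA) and 4641 under vehicle (2191 and 2450). With the replicate block the counts were 5848 and 6907, and with replicates 1 and 2 only 6810 and 7670.

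The changes with both pools overlapped in part. Under R1881, 393 genes rose with both pools and 478 fell with both, against 106.8 and 107.5 for lists drawn independently, and 110 went opposite ways. Under vehicle, 156 rose with both and 94 fell with both, against 51.0 and 58.0, and 177 went opposite ways. The values for independent lists were computed only for the same direction, so the counts of opposite changes have no such reference. Opposite changes may also exceed what independent lists would give, so the shared counts alone do not show that the pools act alike under vehicle. Both pools were compared with the same control libraries, which alone makes the fold changes correlate. Across the 15185 genes, which are not independent replicates, Pearson r was 0.37 under R1881, against 0.48 in simulations with no knockdown effect, and 0.18 under vehicle, against 0.47. The covariance, which the shared controls raise to 0.0488 and 0.0436 in those simulations, was 0.111 under R1881 and 0.0477 under vehicle. The simulations drew each library independently. In the data, libraries of one replicate number deviated together (r 0.37 to 0.80 for E2F1 siRNA and control under vehicle), so the simulated values may be off. Knockdown effects also add variance, so an r below the simulated one does not show less similarity. With no shared library, r was 0.21 for E2F1 siRNA under R1881 against E2F2 siRNA under vehicle, and 0.02 for E2F1 siRNA under vehicle against E2F2 siRNA under R1881. Under vehicle r was 0.33 without control siRNA with vehicle replicate 1, and 0.33 without its replicate 2. No replicate block was fitted to these correlations.

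**Figure D4:**
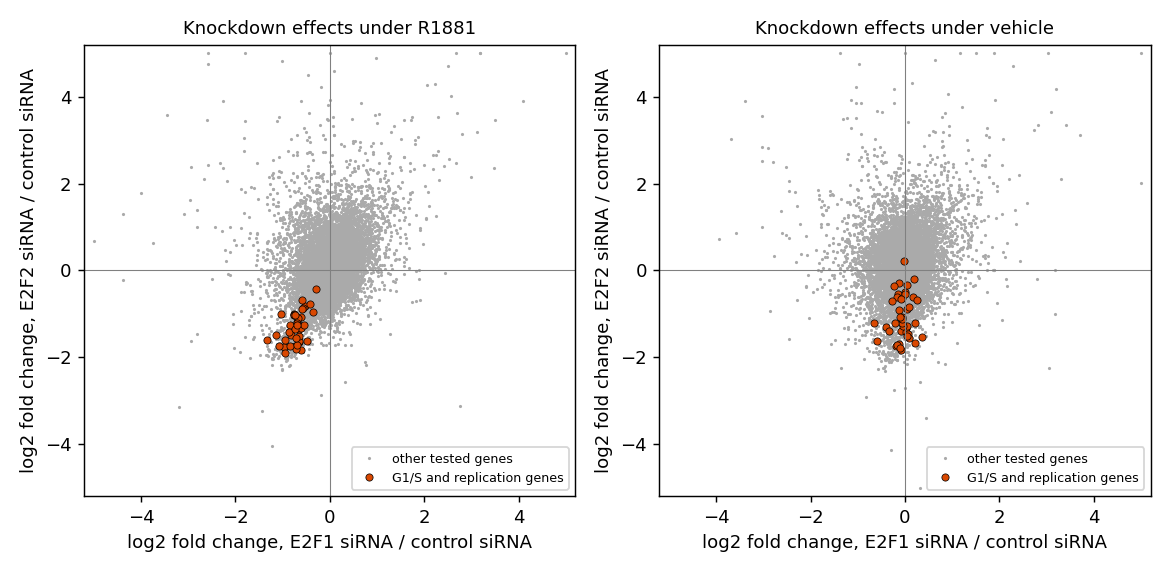
Log2 fold change of each of 15185 genes with E2F1 siRNA (horizontal) against that with E2F2 siRNA (vertical), each over control siRNA, under R1881 (left) and vehicle (right); the 42 G1/S and replication genes are in orange, and values beyond the axes are drawn at the edge. Most orange points lie in the lower left under R1881, where 33 fell with E2F1 siRNA and 40 with E2F2 siRNA.

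With either knockdown the classical androgen response remained. R1881 raised all 35 androgen-induced genes with E2F1 siRNA and all 35 with E2F2 siRNA, and lowered 14 of 16 androgen-repressed genes in each. KLK3 rose 10.7-fold with E2F1 siRNA (log2 3.42 ± 0.13) and 31.4-fold with E2F2 siRNA (4.97 ± 0.14), and TMPRSS2 12.7-fold and 8.75-fold. Against control siRNA, KLK3 under vehicle was 1.88-fold higher with E2F1 siRNA and 2.01-fold lower with E2F2 siRNA. Under R1881 its log2 values against control siRNA were 0.39 ± 0.12 and 0.02 ± 0.12, neither called. The lipid synthesis list rose in 21 of 30 cases with each pool (24 and 23 adjusted over the list alone), and the endoplasmic reticulum stress list rose in 17 and 14 of 25 cases, with CREB3L4 at 2.84-fold and 2.40-fold. With E2F1 siRNA, R1881 raised 4 of 42 G1/S genes (4 adjusted over the list alone), CDC25A, FEN1, SLBP and CDC6, and 12 of 45 G2/M genes (18 adjusted over the list alone). With E2F2 siRNA it raised 24 of 42 G1/S genes (28 adjusted over the list alone) and 37 of 45 G2/M genes (41 adjusted over the list alone), with CDC25A at 2.23-fold and KIF20A at 2.68-fold.

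Among large rises, STEAP4, of the androgen-induced list, had 1 count with E2F1 siRNA and vehicle and 1974 with R1881 (ratio 1991, 95% counting interval 357.0 to 78690). TUBA3D, a tubulin gene outside these lists, had 2 and 640 with E2F2 siRNA (ratio 295.1, interval 81.4 to 2442). SLC2A3 and SLC38A4 were at least 96.5-fold and at least 121.7-fold higher with R1881 in cells with E2F2 siRNA, and SLC2A3 at least 60.9-fold higher with E2F1 siRNA, each against 0 counts. Among falls with R1881 and E2F1 siRNA were CCDC80 (32.1-fold), DAB1, from 137 counts to 1 (ratio 135.8, interval 24.0 to 5403), KCNU1, from 92 to 2 (ratio 45.6, interval 12.3 to 382.2), and KCNK3, at least 18.8-fold lower. With E2F2 siRNA IL1B (-4.81 ± 0.31), CCDC80 (-4.00 ± 0.33) and DAPK1 (-3.99 ± 0.25) fell. With an estimated correlation 5 of 7 lists held with E2F1 siRNA, the calls of the G2/M list (adjusted p = 0.350 with an estimated correlation) and of the glycolysis list (0.527) being lost. With E2F2 siRNA 8 of 10 held, DNA repair (0.568) and replication histones (0.732) being lost. R1881 changed 3009 genes with E2F1 siRNA (1528 higher, 1481 lower) and 3465 with E2F2 siRNA (1791 and 1674). The replicate block gave 4661 and 5501, and replicates 1 and 2 only gave 5829 and 6927.

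The test of the difference between androgen responses compared the R1881 effect with each E2F pool to that with control siRNA. With E2F1 siRNA the R1881 response of the G1/S list was smaller, with a median log2 difference of -0.70. Single members passed in 8 of 42 cases (33 adjusted over the list alone), among them MCM4 (-0.85 ± 0.11, adjusted p = 0.0022), TYMS (-0.80 ± 0.12), CDC6 (-0.84 ± 0.13) and MCM10 (-0.89 ± 0.14). The G2/M list followed with a median of -0.61 and 4 of 45 members (26 adjusted over the list alone), and the DNA repair list with -0.65 and 2 of 32 (18 adjusted over the list alone), CHEK2 and UBE2T. NCAPD3, which R1881 raised from 111.3 ± 3.39 to 1116 ± 47.2 CPM with E2F1 siRNA and from 118.2 ± 4.71 to 297.3 ± 48.2 with control siRNA (SD, n = 3), had a larger response (log2 2.00 ± 0.20, adjusted p = 2.48e-04). MYLK, myosin light chain kinase (2.01 ± 0.23), DUSP27 (2.06 ± 0.36), BST2 (2.03 ± 0.44) and TMPRSS2 (0.68 ± 0.13) also had a higher difference, and TM4SF1 (-1.66 ± 0.31), SERPIND1 (-1.31 ± 0.22), HIST1H2AM (-1.29 ± 0.24) and SLC16A10 (-1.25 ± 0.20) a lower one. A higher difference was not always a stronger rise. R1881 lowered MYLK from 66.4 to 8.01 mean CPM with control siRNA and from 20.9 to 10.1 with E2F1 siRNA. BST2 went from 1.39 to 0.509 with control siRNA and from 2.16 to 3.36 with E2F1 siRNA. DUSP27 went from 2.34 to 2.58 and from 0.730 to 3.44 in that order.

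With E2F2 siRNA the response of IGFBP3, an insulin-like growth factor binding protein (ENSG00000146674.14, chromosome 7, 45912245 to 45921874), turned: R1881 took it from 51.2 ± 7.44 to 12.5 ± 2.61 CPM with control siRNA and from 13.7 ± 1.48 to 28.8 ± 4.25 with E2F2 siRNA (SD, n = 3; log2 difference 3.11 ± 0.24, adjusted p = 8.60e-06). KLK3 (1.03 ± 0.17), of the androgen-induced list, had a larger response. REG4 (2.50 ± 0.50), MYOZ1 (2.09 ± 0.38) and SLC25A34 (1.90 ± 0.41) were higher in the difference, and CXCR4 (-2.10 ± 0.29), FAM65B (-1.84 ± 0.21), BVES (-1.73 ± 0.29) and DST, dystonin (-1.53 ± 0.18), lower. With R1881, REG4 went from 6.03 to 0.634 mean CPM with control siRNA and from 1.39 to 0.835 with E2F2 siRNA. MYOZ1 went from 4.37 to 0.240 and from 11.2 to 2.79 in that order, so both fell less with E2F2 siRNA. The p53 target list was lower in the difference, with a median of -0.42 and 2 of 27 members past the threshold (8 adjusted over the list alone), AEN and DDB2. The G1/S list had a median of -0.21, with 1 of 42 members past the threshold, MCM6 (-0.62 ± 0.12); the call was lost with adjusted p = 0.152 with an estimated correlation.

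With an estimated correlation the G1/S, G2/M, DNA repair, endoplasmic reticulum stress and MYC-driven lists held of 10 called for E2F1 siRNA, and the p53 list of 10 called for E2F2 siRNA. The calls lost had adjusted p = 0.0533 to 0.205 with an estimated correlation for E2F1 siRNA and 0.0729 to 0.380 for E2F2 siRNA. The interferon list, called higher in the difference for E2F1 siRNA (adjusted p = 0.0163), had 0.0588 with the replicate block. In all 104 genes differed for E2F1 siRNA (57 higher, 47 lower) and 135 for E2F2 siRNA (85 and 50). These counts moved with the setting: 696 and 658 with the replicate block, 1844 and 1767 with replicates 1 and 2 only, 339 and 304 with DESeq2, 22 and 60 with no filter on low counts, and 21 and 40 in a fit to the 12 libraries compared. For E2F1 siRNA the count was 63 and 250 without control siRNA with vehicle (replicates 1 and 3), 39 and 29 without control siRNA with R1881 (replicates 1 and 2), 38, 35 and 45 without E2F1 siRNA with R1881 (replicates 1, 2 and 3), and 37 without E2F1 siRNA with vehicle (replicate 1). For E2F2 siRNA it was 80 and 208 without control siRNA with vehicle (replicates 1 and 3), 58 and 56 without control siRNA with R1881 (replicates 1 and 2), 78 and 53 without E2F2 siRNA with R1881 (replicates 1 and 2), and 60, 59 and 74 without E2F2 siRNA with vehicle (replicates 1, 2 and 3).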

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

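Tests chosen only after the result was seen were those of the fall of E2F1, of GC content and length offsets, of 7-mers that occur apart, of levels too low to fall, of E2F1 left after knockdown, of replicate 3 and of the control pool; the first 7-mer test and the counts over other splits were set before their own results were seen, as was the criterion for the offsets, a setting added after the data were seen.

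The difference between R1881 responses itself was tested, and it passed for 104 genes with E2F1 siRNA and 135 with E2F2 siRNA. It also passed, with an estimated correlation, for 5 lists with E2F1 siRNA: G1/S and replication (median log2 difference -0.70, adjusted p = 3.90e-04), G2/M and mitosis (-0.61, 0.0027), DNA repair (-0.65, 0.0284), endoplasmic reticulum stress (0.24, 0.0046) and MYC-driven genes (-0.38, 9.21e-04). With E2F2 siRNA it passed for the p53 targets (-0.42, 5.72e-04). For these gene counts the criterion set beforehand, a share of splits under 0.05, was not met. Regrouping therefore leaves chance open for them. In each case 11 of 100 splits, the real one included, gave as many genes, with the highest other split at 2516 for E2F1 siRNA and 3547 for E2F2 siRNA. Counts that many times the real one point to a structure of the samples, which was looked for after the counts were seen. Of the other splits 19 kept the libraries of each siRNA together within a treatment, so they hold the knockdown effect itself; 9 of them reached the real count for E2F1 siRNA and 10 for E2F2 siRNA. The 80 splits that mixed the siRNAs within both treatments place that effect within groups, so they are no measure of chance alone either; 1 reached the real count for E2F1 siRNA, the one with 2516 genes, whose structure was not identified, and 0 for E2F2 siRNA. The splits were counted in a model without the replicate block, with which the real counts were 696 and 658.

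The 9 comparisons of 3 against 3 libraries have 10 splits each, too few for a share under 0.05. For R1881 with control siRNA 1 of the 10 splits, the real one, reached its 4105 genes (highest other 1), and so it was for E2F1 siRNA under R1881 (1; 1418, highest other 0), E2F2 siRNA under R1881 (1; 4601, 0) and under vehicle (1; 4145, 0), the E2F pools against each other under R1881 (1; 3648, 0) and vehicle (1; 4641, 0), and R1881 with E2F1 siRNA (1; 3009, highest other 1) and with E2F2 siRNA (1; 3465, 0). For E2F1 siRNA under vehicle 2 splits reached the 802 genes of the real one. The other called 2333, which points to a structure of the samples that was identified only in part. That split puts both replicate 3 libraries on one side, but so do 3 splits that called 0. No split was counted with the replicate block, with which the real count was 1934.

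The first pattern weighed is that more genes changed with E2F2 siRNA (4601 under R1881) than with E2F1 siRNA (1418). E2F2 siRNA also lowered E2F1, but E2F1 siRNA lowered it further, and 2588 genes (56.2% of those called with E2F2 siRNA under R1881) differed directly from E2F1 siRNA and lay further from control, which argues against the fall of E2F1 as the whole cause. GC content and length are argued against as the whole cause as well, since offsets that remove both trends gave 7360 genes with E2F2 siRNA and 3704 with E2F1 siRNA. With the block added the counts were 8287 and 4869. In both settings the counts lay closer in ratio than without the offsets. They also lay closer without offsets, with the replicate block alone (6919 and 3022) and with replicates 1 and 2 only (7828 and 4487). The closer ratio therefore cannot tell whether a part of the excess goes with GC content or length. Silencing of other mRNAs through matches to the siRNA seeds stays open: of the 20 7-mers whose presence in 3' UTRs went with the strongest falls, 11 were in E2F2 mRNA against 4.72 expected (one-sided Fisher exact, or hypergeometric, p = 0.0024), which met the criterion set beforehand, but 18 of the 20 occur together, so that this p is not valid, and among 20 that occur apart 6 were in E2F2 mRNA (p = 0.327). The siRNA sequences are not in the labels, and the biological alternative, a wider role of E2F2 in these cells, cannot be told apart from such matches with 1 pool per gene.

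The same exact 7-mer test for E2F1 siRNA gave 7 of 20 in E2F1 mRNA against 2.60 expected (p = 0.0104), or 4 (p = 0.258) among 7-mers that occur apart. As a check on the wrong target with the same exact test, 1 of the 20 7-mers for E2F2 siRNA was in E2F1 mRNA (p = 0.939) and 7 of the 20 for E2F1 siRNA were in E2F2 mRNA (p = 0.172).

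The second pattern is that E2F1 siRNA lowered the G1/S list under R1881 (33 of 42) and not under vehicle (3 of 42), a difference that passed its own test (median -0.70). Levels too low to fall under vehicle are argued against by E2F2 siRNA, with which 35 of the 42 (83.3%) fell under vehicle. E2F1 left after knockdown was not higher under vehicle: with E2F1 siRNA the log2 ratio of R1881 over vehicle was 0.50 (adjusted p = 0.0556). Replicate 3 is argued against by a median of -0.65 with replicates 1 and 2 only. The biological explanation that the design names, a need for E2F1 in the rise of these genes with androgen, was not tested further and stays open, and CDC25A, RRM2 and MCM3 fell under vehicle too.

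The third pattern is that the interferon list was higher with both targeting pools than with control siRNA, under both treatments. With replicates 1 and 2 only the 4 medians were 0.93 and 1.51 under R1881 (E2F1 and E2F2 siRNA) and 0.78 and 1.41 under vehicle, so the lowest, 0.78, argues against replicate 3 as the cause. A control pool that holds these genes low would put both targeting pools at one level; the pools differed by a median of -0.27 under R1881 and -0.47 under vehicle, with adjusted p = 0.413 and 0.260 with an estimated correlation, so this stays open. A response to the siRNA molecules of both pools and an effect of lower E2F activity cannot be told apart here with 1 pool per gene. No group went without siRNA, so the effect of the control pool itself was not measured.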

How the results depend on the processing

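Replicates 1 and 2 only, the GC and length offsets, and those offsets with the replicate block were chosen after seeing the data; the other settings were planned. Values below run in the order R1881 with control siRNA; E2F1 siRNA and E2F2 siRNA under R1881; E2F1 siRNA and E2F2 siRNA under vehicle; E2F1 against E2F2 siRNA under R1881 and under vehicle; R1881 with E2F1 siRNA and with E2F2 siRNA; and the difference in R1881 response with E2F1 siRNA and with E2F2 siRNA. Gene counts were 4105, 1418, 4601, 802, 4145, 3648, 4641, 3009, 3465, 104 and 135. With the replicate block they were 6392, 3022, 6919, 1934, 6873, 5848, 6907, 4661, 5501, 696 and 658. With replicates 1 and 2 only they were 7205, 4487, 7828, 2864, 6962, 6810, 7670, 5829, 6927, 1844 and 1767. With GC and length offsets they were 6758, 3704, 7360, 2460, 6647, 6366, 7286, 5263, 6061, 1258 and 1058, and with these and the block 7896, 4869, 8287, 3519, 7729, 7423, 8215, 6279, 7036, 2124 and 1953. With adjusted p under 0.01 they were 2666, 714, 2971, 354, 2500, 2128, 2961, 1977, 2358, 25 and 37, and with a 2-fold threshold added 1245, 255, 1345, 220, 1239, 1020, 1457, 1133, 1200, 25 and 53, as stricter thresholds must give fewer.

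Fits to the groups compared only gave 1842 genes for R1881 with control siRNA, 2131 for E2F1 siRNA under R1881, 17 and 1793 for E2F1 and E2F2 siRNA under vehicle, and 21 and 40 for the differences in response. With no low-count filter E2F1 siRNA gave 903 under R1881 and 462 under vehicle, and the differences 22 and 60, with more genes tested. DESeq2 gave 339 and 304 for the differences. The cause was not tested for the block, replicates 1 and 2, the offsets, the fits to the groups compared only or DESeq2. RLE scaling, the filter of CPM at least 1 and limma-voom left all 11 counts within 1.5 times. Leaving out 1 library in turn gave 872 to 1075 genes for E2F1 siRNA under R1881, 445 to 1028 under vehicle, 29 to 250 and 53 to 208 for the differences in response; the 2 libraries left in that group are assumed to vary like the other groups. Of the 4105 genes called for R1881 with control siRNA 2690 were called in every such fit, of the 1418 and 4601 for E2F1 and E2F2 siRNA under R1881 669 and 2945, of the 802 and 4145 under vehicle 335 and 2536, and of the 104 and 135 differences 27 and 44.

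With an estimated correlation the lists called went from 11 to 7 for R1881 with control siRNA, 14 to 9 and 9 to 5 for E2F1 and E2F2 siRNA under R1881, 10 to 1 and 10 to 5 under vehicle, 9 to 4 and 10 to 4 for the pools against each other, and 10 to 5 and 10 to 1 for the differences. With fry they were 17 for E2F2 siRNA under R1881, 14 for the pools against each other under R1881, 11 for R1881 with E2F1 siRNA and 5 for the difference with E2F2 siRNA. The camera settings treat correlation between genes differently. Camera tests a list against the other genes, while fry tests it against no change, so their counts answer different questions. The cause of the differences was not tested further. The similarity under R1881 (r 0.37) was 0.45 among genes with an average log2 CPM of at least 1, 0.40 with replicates 1 and 2 only, 0.21 with no shared library and 0.41 to 0.43 without 1 control library; under vehicle (0.18) it was 0.0199 with no shared library and 0.19 to 0.33 without 1 control library.

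The knockdown of each target kept its direction and its call in every setting run. Of 796 values of named genes 607 kept their direction and their side of the threshold in every setting, and of 220 list results 118; among these no called value changed sign. With the replicate block 40 gene values newly passed the threshold, 2 list results newly passed it and 6 lost it, and the block changed no other call among them. Depth limits values that rest on few counts, among them the E2F2 level after E2F2 siRNA, with 0 to 5 counts per library.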

Other observations

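The tests of ribosomal protein genes, translation factors, MALAT1 and MYC were all chosen after the values were seen.

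Ribosomal protein genes, which were in no list, were lower with E2F2 siRNA. Of 84 tested, 73 fell under R1881 (median log2 -0.63, limma camera p = 0.0080 with an estimated correlation) and 77 under vehicle (median -0.79, p = 8.89e-04). With E2F1 siRNA the medians were 0.00 under R1881 and -0.03 under vehicle, and neither passed (camera in limma with an estimated correlation, p = 0.935 and 0.961). These p-values are not adjusted, and the genes were not tested with the GC and length offsets. Across genes, log2 changes with E2F2 siRNA correlated with log2 gene length (r 0.09 under R1881, 0.14 under vehicle). With GC content r was -0.11 and -0.26. The elongation factor genes EEF1A1 and EEF2 fell with E2F2 siRNA to 57.7% and 61.4% of control under R1881 and to 49.4% and 47.9% under vehicle. MYC, whose product drives ribosome synthesis, fell to 41.9% and 41.6% (log2 -1.26 ± 0.20 in both, n = 3). With E2F1 siRNA MYC was not called (log2 -0.44 ± 0.19 under R1881 and 0.07 ± 0.19 under vehicle).

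MALAT1 rose 2.95-fold with E2F2 siRNA under R1881 (log2 1.56 ± 0.32, adjusted p = 0.0017) and 2.60-fold under vehicle (log2 1.38 ± 0.32, adjusted p = 0.0046). With E2F1 siRNA it took 2.00 ± 0.342% of counts under R1881 and 2.44 ± 0.891% under vehicle (SD, n = 3).

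The first principal component of the 18 libraries held 39.8% of the variance, the second 23.9% and the third 13.0%. GC content and gene length took 33.8% to 74.3% of the variance across genes of the replicate 3 deviations from the other libraries of the group (12097 genes). For replicates 1 and 2 the share was 7.6% to 67.8%.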
